A study of Mus musculus with 8 samples.

How the data were processed

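Gene expression was measured on 8 2-colour microarrays, each carrying RNA of intestinal crypt cells from Lgr4 null mice in 1 dye and wild-type RNA in the other. Lgr4 encodes a receptor for R-spondins, secreted proteins that strengthen Wnt signalling, and the null allele is a gene trap on the outbred CD1 background, per the labels. The 4 groups of 2 arrays each were crypts on day 0, after 0.5 days and after 1 day of culture (day 0.5 and day 1 below), and crypts after 1 day with LiCl, a salt that inhibits the kinase GSK3 and so raises beta-catenin. Per the labels' protocols, total RNA was purified with a MirVana kit, amplified as aminoallyl antisense RNA, coupled to Cy5 or Cy3 and hybridised to MEEBO arrays of long oligonucleotide probes against mouse exons. Groups and replicate numbers came from the sample titles. The labels do not say whether the 2 arrays of a group hold separate cultures or animals, so every p-value measures the spread between these arrays, which may be technical only.

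The authors deposited log2 values (the base is assumed), made as 1 log ratio of the 2 channels per probe and array. No intensities came with the values used here, so signal over background is unknown. The background correction, the normalization and the base of the logarithm are not given in the sources used here. Values were taken as log2 ratios, and every fold assumes that base. The array medians lay between -0.006 and 0.001, so the deposited ratios were already centred. Null over wild type is the likely direction of the ratio. It rests on the labels, where channel 1 is the null RNA of each array, and on lower values of Paneth cell genes, the cells named in the series title. Arrays of 1 group with opposite labelled dyes correlated above 0, so no array was turned by its dye. The direction of the LiCl arrays is not settled: each correlated below 0 with every array of the other groups, and the labels and the series text differ on what their other channel holds (wild-type crypts with LiCl, or control cells). Their values are given as deposited. Where another group enters the comparison, the number of genes called and a part of the other values are also given with the sign turned. Per the labels, the null RNA was in Cy5 on both arrays of day 0.5, although the series text speaks of dye swaps throughout. The null dye was Cy5 on replicate 1 and Cy3 on replicate 2 of day 0 and day 1, and the reverse with LiCl.

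The table held 38467 probes with a value on every array. The platform's gene table gave 1 symbol for 22941 probes, several for 0 and none for 15526. All 22941 gene identifiers matched the reference gene table, and 0 symbols changed. Probes of control series were left out, among them 636 with a gene name, which left 22305 probes of 15123 genes. Of these genes 10015 had 1 probe and 5108 had several, at most 15, which were averaged. As a check of the naming, 268 pairs of probes of the same gene that varied over the arrays (SD above 0.5) had a median correlation of 0.897, against 0.119 for 268 pairs from different genes. These correlations run over the 8 arrays. Columns of other series numbered 0.

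Each array was centred on its median. limma 3.58.1 in R 4.3.3 fitted all 8 arrays together, with a mean for each of the 4 groups and a term for the labelled dye of the null RNA, followed by eBayes (3 residual degrees of freedom, 4.09 from the prior). The comparisons were each group mean against 0, the mean of the 4 groups against 0, and the changes of the ratio from day 0 to day 0.5, from day 0 to day 1, and from day 1 to day 1 with LiCl. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 15123 genes. Errors given as ± are limma standard errors of the fitted value, on the log2 scale: a group of 2 arrays, the mean of the 4 groups (median over genes 0.061) or a change of the ratio (0.178 from day 0 to day 0.5 and 0.165 for the others). At day 0.5, where both arrays carry the null RNA in Cy5, the fitted value is adjusted for the dye term and is not the mean of the arrays (for Lyz1 -3.41 and -3.55), which also enters the mean of the groups and the change from day 0 to day 0.5. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the figures.

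The comparisons, the alternatives, the rule for named genes and 27 gene lists were fixed before the data were examined. The lists were the target Lgr4, Paneth cell, crypt base stem cell, reserve stem cell, Wnt target, Wnt ligand and receptor, Notch pathway, secretory progenitor, goblet cell, enteroendocrine cell, tuft cell, enterocyte, fetal-type epithelium, cell cycle, p53 and cell death, unfolded protein stress, immediate early and heat shock, mesenchyme, endothelium, immune cell, red blood cell, glia, cholesterol synthesis, antimicrobial and inflammatory, interferon response, hypoxia and glycolysis, and ribosomal protein genes. A shift of each list with at least 5 measured genes was tested with limma's camera (preset correlation 0.01) and adjusted over the 23 lists tested. Lists that share members, such as Lgr5 and Rnf43 in the stem cell and Wnt target lists, are not independent. Camera was also run with an estimated correlation, which called only the immune, antimicrobial, interferon and enterocyte lists at day 0. In that setting its p-values rest on the 3 residual degrees of freedom, so small ones are hard to reach. The estimate was below the preset for lists such as enterocyte (-0.031) and ribosomal protein (-0.037), and above it for others such as Paneth cell (0.127). A weaker adjusted p there is thus not by itself a sign of correlated members. Named genes were the 10 highest and 10 lowest past the threshold with the same sign on both arrays of the group (on all 8 arrays for the mean of the groups, and 5 each for the changes), and up to 4 genes of smallest p from each list, or all Paneth and stem cell genes.

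Replicate numbers were checked for pairing from correlations, not from calls. The difference between replicate 1 and replicate 2 correlated across all 38467 probes in each of the 3 pairs of groups without LiCl, with r from 0.23 to 0.242, and in the 3 pairs with LiCl as deposited, with r from 0.176 to 0.222 (probes are not independent replicates). A pairing by replicate number thus rests on the data alone, since the labels name no shared batch. The main fit holds no term for it, so the main counts, errors and p-values ignore it. A replicate block was run as an alternative. With the sign of the LiCl arrays turned, the latter 3 lie between -0.222 and -0.176, so a positive correlation for LiCl needs the sign as deposited. The labelled dyes of the LiCl pair run in reverse to day 0 and day 1. A dye bias would then give r below 0 with those groups under the true sign. These correlations therefore do not settle the sign of the LiCl arrays.

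Alternatives were no dye term, a replicate block beside the dye term, day 0.5 replicate 2 taken as a dye swap, no centring, arrays scaled to equal spread, robust eBayes, each probe alone, the arrays of a group alone, a 2-fold rule, pair means, 3 groups without LiCl, other gene set tests (camera with an estimated correlation, fry, 1 probe per gene), and each array left out in turn. Added after the data were seen were a turned sign of the LiCl arrays, the LiCl arrays left out, a replicate block in place of the dye term, named control probes averaged in, and the immune list without its MHC class II genes. The model was tested on simulated data with 200 of 15123 genes changed. At day 0 it called 46.3% of changes of 0.5 and 100% of changes of 1 on the log2 scale, at day 0.5 8.96% and 97%, at day 1 31.3% and 98.5%, and with LiCl 23.9% and 94%. Of the simulated calls at day 1, 11.6% were false, and 5.75% at day 0. The simulated errors were independent between genes and arrays, with the fitted dye effect and no replicate component. The 200 changed genes were also fewer than the 3103 called at day 1. These rates may therefore not carry over to the real data. The number of arrays limits the precision: the median standard error of a gene was 0.117 at day 0, day 1 and day 1 with LiCl and 0.135 at day 0.5. The rule for outlying arrays needs at least 4 in a group and was not applied, and array weights were not fitted.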

Results

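Gene expression in Lgr4 null and wild-type intestinal crypts was compared directly on 8 arrays, 2 for each of 4 culture groups: day 0, day 0.5, day 1 and day 1 with LiCl. Each value is a log ratio, null over wild type in its likely direction and taken as log2, for 15123 genes. Lgr4 itself, which would check the labels first, was not analysed here, because no probe used carries its name. The spread of the ratios over all probes was largest at day 1 (SD 0.473 and 0.441 on the 2 arrays), between 0.296 and 0.335 at day 0 and day 0.5, and 0.283 and 0.248 with LiCl. Correlations across probes were 0.308 to 0.737 between the arrays of a group and 0.154 to 0.49 between groups without LiCl. The LiCl arrays correlated below 0 with all 6 other arrays (r from -0.493 to -0.0855 over 12 pairs), so the direction of their ratio is not settled. Genes and probes are not independent replicates in these correlations.

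At day 0, genes of Paneth cells, the antimicrobial secretory cells of the crypt base, were lower in null crypts. Of 14 measured Paneth cell genes 9 were lower (10 passed adjusted over the list alone, 1 of them higher), with a median of -1.05. Lyz1, the Paneth cell lysozyme, stood at -4.20 ± 0.14, an 18.4-fold difference (adjusted p = 0.000148, limma). Defa3, an alpha-defensin, was at -3.16 ± 0.15, the lectin Itln1 at -1.24 ± 0.10 and Mmp7, the protease that activates defensins, at -1.06 ± 0.15. Defa3 and Defa31 (-3.49 ± 0.13) belong to a family of near-identical genes that 1 probe may not tell apart. The direction of the ratio at all 3 days was set partly from these genes, so their lower values are not independent evidence of it. The 4 probes of Lyz2 disagreed, with values from -3.37 to 0.05. The list shifted down with a camera adjusted p of 9.62e-11, and adjusted p = 0.0837 with an estimated correlation.

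MHC class II genes and other immune cell genes were also lower at day 0. Of 11 immune cell genes 7 were lower (9 adjusted over the list alone), with a median of -0.73. H2-Ab1 at -2.73 ± 0.14 and H2-Aa at -2.59 ± 0.18 encode chains of MHC class II, Cd74 at -2.61 ± 0.17 its invariant chain, and Cd3g at -1.25 ± 0.11 a part of the T cell receptor complex. In the other direction, 6 of 15 antimicrobial and inflammatory genes were higher (8 adjusted over the list alone, median 0.43). These included Reg3b at 3.60 ± 0.15 (12.1-fold) and Reg3g at 3.08 ± 0.15, lectins that kill gut bacteria, and the serum amyloid genes Saa3 at 2.78 ± 0.14 and Saa1 at 2.34 ± 0.12. Interferon response genes were higher in 3 of 10 cases (9 adjusted over the list alone, median 0.68), such as Rsad2 at 1.40 ± 0.16 and Ifit3 at 1.20 ± 0.10. Camera adjusted p was 1.51e-13 for the immune, 1.09e-12 for the antimicrobial and 6.69e-11 for the interferon list, and each had adjusted p = 0.0491 with an estimated correlation.

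Genes of absorptive enterocytes were higher at day 0 for 2 of 16 (5 adjusted over the list alone, median 0.40). These were Cyp3a11, a drug-metabolising cytochrome, at 2.20 ± 0.14 and the glucose transporter Slc2a2 at 0.60 ± 0.11. This list had a camera adjusted p of 3.95e-08, and adjusted p = 0.0491 with an estimated correlation. Crypt base stem cell genes were lower for 2 of 15 (6 adjusted over the list alone, median -0.27), Cdca7 at -1.08 ± 0.20 and Rnf43, a Wnt-induced ubiquitin ligase, at -0.50 ± 0.09. The stem cell marker Lgr5 at -0.23 ± 0.11 did not pass. Of 24 Wnt target genes 2 were lower, Ccnd1 at -0.68 ± 0.10 and Rnf43 (2 adjusted over the list alone, median -0.06). In camera the adjusted p was 0.000468 for the stem cell list and 0.0204 for the Wnt target list, with adjusted p = 0.0884 and adjusted p = 0.162 with an estimated correlation. Mesenchyme genes were lower for 2 of 13 (2 adjusted over the list alone, median -0.13), Vim at -0.58 ± 0.10 and the matrix gene Dcn at -0.51 ± 0.09. Ribosomal protein genes were lower for 1 of 15 (5 adjusted over the list alone, median -0.29), Rpl4 at -0.63 ± 0.11. Their camera adjusted p was 0.0132 and 4.85e-06, with adjusted p = 0.132 and adjusted p = 0.0644 with an estimated correlation. The p53 list, the immediate early list and the hypoxia list each had 2 higher genes, among them Trp53inp1 at 0.68 ± 0.11, the growth-response gene Fos at 0.99 ± 0.10 and the glycolytic enzyme Hk2 at 1.16 ± 0.10 (3, 2 and 5 adjusted over the list alone; medians 0.18, 0.14 and 0.23). By camera the adjusted p was 0.00479, 0.00132 and 0.00133, with adjusted p = 0.12, 0.12 and 0.1 with an estimated correlation. The cell cycle list was not called at day 0 (camera adjusted p = 0.234, median -0.11), and 1 of 23 was higher and 1 lower (4 adjusted over the list alone, 3 of them higher). Of the 3 red blood cell genes, too few for a list test, Hba-a1 was lower at -0.60 ± 0.10 (2 adjusted over the list alone).

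In all, limma called 337 genes at day 0, 185 higher and 152 lower in null crypts, of which 61 and 48 differed at least 2-fold. Others at the extremes were Car4 at 2.78 ± 0.19 and Fabp6, the bile acid binding protein of the ileum, at 2.23 ± 0.12. Among the lowest were Ubd at -2.56 ± 0.15 and Ido1 at -2.52 ± 0.17, both induced by interferon gamma. The count was 26 and 30 without day 0 replicate 1 and 2, 224 without either day 0.5 array, 193 without either day 1 array, 160 with arrays scaled to equal spread and 610 with the replicate block, and 16 and 12 of the 20 genes at the extremes still passed without replicate 1 and 2. The Wnt target list lost its call without either day 0 array (adjusted p = 0.0541 and 0.116), the p53 list without replicate 1 (0.099) and the mesenchyme list without replicate 2 (0.255).

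**Figure D1:**
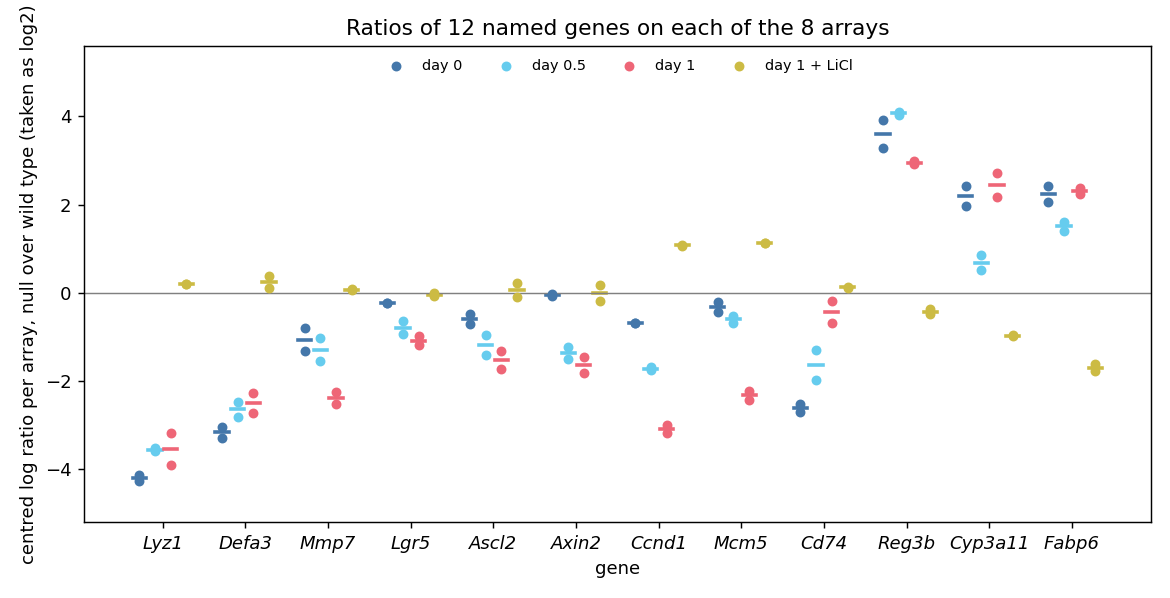
Centred log ratio of null over wild type (taken as log2, vertical axis) of 12 genes on each of the 8 arrays, with points for single arrays and bars for the mean of the 2 arrays, without the dye adjustment. Lyz1 lies at -4.26 and -4.14 at day 0 and at 0.19 and 0.21 with LiCl, and Ccnd1 at -3.18 and -2.99 at day 1 and at 1.08 and 1.07 with LiCl.

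At day 0.5, Paneth cell genes were again lower in null crypts, for 4 of 14 genes (9 adjusted over the list alone, 8 of them lower, median -0.71). Lyz1 was at -3.41 ± 0.16, a 10.7-fold difference, Defa3 at -2.71 ± 0.17 and Mmp7 at -1.42 ± 0.17. Crypt base stem cell genes were lower for 1 of 15, Rnf43 at -1.06 ± 0.11 (8 adjusted over the list alone, median -0.47), while Ascl2, a stem cell regulator, at -1.13 ± 0.18 and Lgr5 at -0.77 ± 0.13 did not pass. With the replicate block both passed (adjusted p = 0.0405 and 0.0484). Wnt target genes were lower for 3 of 24 (8 adjusted over the list alone, median -0.07). They were Ccnd1, which drives entry into the cell cycle, at -1.69 ± 0.11, Axin2, a feedback inhibitor of Wnt signalling, at -1.38 ± 0.16, and Rnf43. Camera adjusted p was 3.04e-08, 3.57e-07 and 0.00012 for these lists, and each had adjusted p = 0.0946 with an estimated correlation. Among mesenchyme genes Vim was higher at 0.77 ± 0.11 (1 of 13, 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.373). Immune cell genes were lower for 2 of 11, Cd74 at -1.76 ± 0.19 and H2-Ab1 at -1.21 ± 0.16 (3 adjusted over the list alone, median -0.07; camera adjusted p = 0.00788). This list had adjusted p = 0.201 with an estimated correlation.

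The enterocyte, goblet cell, unfolded protein and antimicrobial lists shifted up at day 0.5. Of 16 enterocyte genes 2 were higher, the apolipoproteins Apoa1 at 1.37 ± 0.13 and Apoa4 at 1.10 ± 0.16 (7 adjusted over the list alone, median 0.53). Of 12 goblet cell genes the mucus protein gene Zg16 was higher at 1.95 ± 0.18 (7 adjusted over the list alone, 6 of them higher, median 0.36). Of 13 genes of unfolded protein stress the chaperone Pdia4 was higher at 1.12 ± 0.12 (6 adjusted over the list alone, median 0.41). Antimicrobial genes were higher for 2 of 15, Reg3b at 3.99 ± 0.17 and Reg3g at 2.35 ± 0.18 (5 adjusted over the list alone, median 0.10). For these 4 lists camera gave an adjusted p of 1.67e-07, 0.00266, 8.65e-05 and 0.000231, with adjusted p = 0.0946, 0.108, 0.0946 and 0.0946 with an estimated correlation. Hypoxia genes were higher for 1 of 13, the stress gene Ndrg1 at 1.75 ± 0.15 (1 adjusted over the list alone, median 0.11; camera adjusted p = 0.0488). That list had adjusted p = 0.201 with an estimated correlation.

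A further 5 lists shifted at day 0.5 although limma called 0 of their genes. The cell cycle list shifted down (median -0.20, camera adjusted p = 2.15e-05), with 3 genes adjusted over the list alone and 7 at an unadjusted p under 0.05, and adjusted p = 0.102 with an estimated correlation. Ribosomal protein genes also shifted down (median -0.35, camera adjusted p = 7.63e-05), with 3 genes adjusted over the list alone and 5 unadjusted, and adjusted p = 0.0946 with an estimated correlation. Enteroendocrine cell genes shifted up (median 0.31, camera adjusted p = 0.000325), with 4 adjusted over the list alone and 8 unadjusted, and adjusted p = 0.238 with an estimated correlation. Interferon response genes shifted up (median 0.36, camera adjusted p = 0.00084), with 3 adjusted over the list alone and 5 unadjusted, and adjusted p = 0.0971 with an estimated correlation. Genes of fetal-type epithelium, 9 measured, shifted up (median 0.19, camera adjusted p = 0.0435), with 0 adjusted over the list alone and 3 unadjusted, and adjusted p = 0.238 with an estimated correlation.

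limma called 66 genes at day 0.5, 42 higher and 24 lower, of which 33 and 17 differed at least 2-fold. Hyou1, a chaperone of the endoplasmic reticulum, at 1.97 ± 0.13 and the potassium channel subunit Kcne3 at -1.52 ± 0.17 were among the extremes. Eef2, at -1.59 ± 0.12, rests on 3 probes that disagreed (-1.95, 0.11 and -2.92). The count was 9 without either day 0 array, 37 and 38 without day 0.5 replicate 1 and 2, 26 without either day 1 array, 24 with scaled arrays, 237 with the replicate block, 341 with no dye term and 321 with replicate 2 taken as a dye swap. Of the 20 genes at the extremes 9 still passed without either day 0 array, 15 and 10 without day 0.5 replicate 1 and 2, and 16 without either day 1 array. Without either day 0.5 or either day 1 array the fetal-type list (adjusted p from 0.104 to 0.128) and the hypoxia list (from 0.0819 to 0.132) lost their calls, as did the enteroendocrine list without day 0.5 replicate 2 (0.0603).

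Among the tested lists, cell cycle genes had the largest median shift at day 1. All 23 measured cell cycle genes were lower in null crypts (23 adjusted over the list alone, median -1.499). They included Mcm2 at -2.42 ± 0.12 and Mcm5 at -2.32 ± 0.10, parts of the helicase that opens DNA for replication, Birc5, a mitotic survival protein, at -2.36 ± 0.10, and the mitotic kinase Aurka at -2.03 ± 0.11. Ribosomal protein genes were lower for 13 of 15 (13 adjusted over the list alone, median -0.87), such as Rplp0 at -1.41 ± 0.10 and Rpl4 at -1.37 ± 0.11. Camera adjusted p was 3.47e-21 and 2.76e-08, and both lists had adjusted p = 0.0618 with an estimated correlation.

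Crypt base stem cell genes were lower at day 1 for 8 of 15 (8 adjusted over the list alone, median -0.69). Cdca7 was at -2.84 ± 0.20, the ion transporter Slc12a2 at -2.44 ± 0.10, Smoc2 at -1.86 ± 0.14, Ascl2 at -1.52 ± 0.16 and Lgr5 at -1.09 ± 0.11. Wnt target genes were lower for 9 of 24 (10 adjusted over the list alone, 1 of them higher, median -0.32), led by Ccnd1 at -3.08 ± 0.10, 8.48-fold, Ccnd2 at -2.56 ± 0.12 and Axin2 at -1.64 ± 0.14. Of the Paneth cell genes 7 were lower and 2 higher (10 adjusted over the list alone, 2 of them higher, median -0.76). Lyz1 at -3.54 ± 0.14 (11.6-fold) and Mmp7 at -2.38 ± 0.15 were lower, while the stress-induced gene Nupr1 at 1.79 ± 0.11 and Mptx1 at 1.01 ± 0.17 were higher. Camera gave an adjusted p of 4.18e-06, 0.000503 and 0.00177, with adjusted p = 0.0776, 0.144 and 0.197 with an estimated correlation. Of 4 reserve stem cell genes, too few for a list test, Lrig1 at -1.08 ± 0.14 and Hopx at -2.58 ± 0.38 were lower (2 adjusted over the list alone). Hopx has 1 probe, whose replicate values differed.

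The enterocyte, enteroendocrine, goblet cell and fetal-type lists shifted up at day 1. Of 16 enterocyte genes 10 were higher (12 adjusted over the list alone, median 0.89), among them Cyp3a11 at 2.45 ± 0.14, Vil1 of the brush border at 1.32 ± 0.11 and Apoa1 at 1.19 ± 0.11. Of 18 enteroendocrine genes 10 were higher (12 adjusted over the list alone, median 0.75), such as the hormone genes Ghrl at 1.40 ± 0.11 and Sst at 1.08 ± 0.11. Of 12 goblet cell genes 7 were higher and 1 lower (8 adjusted over the list alone, median 0.76), with Zg16 at 2.30 ± 0.16 and the trefoil factor Tff3 at 1.18 ± 0.10 higher and the chemokine gene Ccl6 at -0.71 ± 0.10 lower. Of 9 fetal-type genes 4 were higher (4 adjusted over the list alone, median 0.35), including the cornified envelope gene Sprr1a at 2.65 ± 0.10. Camera adjusted p was 1.19e-08, 1.14e-07, 0.00177 and 0.00426, with adjusted p = 0.0618, 0.168, 0.144 and 0.168 with an estimated correlation.

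Stress and metabolic lists also shifted up at day 1. The p53 list had 6 higher genes and 1 lower of 12 (8 adjusted over the list alone, 7 of them higher, median 0.44), with Apaf1, a scaffold of the apoptosome, at 1.08 ± 0.12 and the cell cycle inhibitor Cdkn1a at 0.86 ± 0.13. Cholesterol synthesis genes were higher for 5 of 11 (6 adjusted over the list alone, median 0.33), with Dhcr7 at 1.85 ± 0.15. Unfolded protein stress had 2 higher and 1 lower of 13 (6 adjusted over the list alone, 5 of them higher, median 0.37), Pdia4 at 0.73 ± 0.10, Atf3 at 0.64 ± 0.12 and the asparagine synthetase Asns at -0.56 ± 0.10. Hypoxia genes were higher for 3 and lower for 2 of 13 (6 adjusted over the list alone, 4 of them higher, median 0.32), with Ndrg1 at 1.63 ± 0.13 and Pdk1 at -1.01 ± 0.13. For these lists camera's adjusted p was 0.0022, 0.0018, 0.0315 and 0.0383, with adjusted p = 0.144, 0.168, 0.177 and 0.179 with an estimated correlation.

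The other 10 tested lists were not called at day 1 (camera adjusted p from 0.119 to 0.968). Of 27 Wnt ligand and receptor genes 3 were higher and 2 lower (5 adjusted over the list alone, median -0.00), with the co-receptor Lrp6 at 0.85 ± 0.14 and the receptor Fzd7 at -0.61 ± 0.10. Of 13 Notch pathway genes Notch1 at -1.42 ± 0.12 and Nrarp at -0.91 ± 0.16 were lower (2 adjusted over the list alone, median -0.03). Of 7 secretory progenitor genes Neurog3 was lower at -0.93 ± 0.17 (1 adjusted over the list alone, median 0.04). Among 13 immediate early genes 4 were higher (6 adjusted over the list alone, 2 of them lower, median -0.03). Among 15 antimicrobial genes 3 were higher (3 adjusted over the list alone, median 0.03), led by Reg3b at 2.96 ± 0.15. Among 10 interferon genes Irf7 at 0.92 ± 0.10 was higher and Ifit2 at -0.47 ± 0.11 lower (2 adjusted over the list alone, median 0.21). Markers of other cell types gave 1 higher mesenchyme gene of 13, Vim at 1.02 ± 0.10 (1 adjusted over the list alone, median 0.03), and 1 lower immune cell gene of 11, H2-Ab1 at -0.65 ± 0.14 (1 adjusted over the list alone, median -0.04). limma called 0 of 8 tuft cell, 0 of 6 endothelium, 0 of 3 red blood cell and 0 of 2 glia genes, with 1 in each list at an unadjusted p under 0.05 and 0, 0, 1 and 0 adjusted over the list alone.

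limma called 3103 genes at day 1, 1418 higher and 1685 lower, of which 330 and 542 differed at least 2-fold. The highest were the placental hormone genes Prl2c2 at 3.95 ± 0.20, Prl2c3 at 3.76 ± 0.16 and Prl2c5 at 3.73 ± 0.14, near-identical copies whose probes may not be specific, and Prl2a1 at 3.18 ± 0.11. Among the lowest were the arginine methyltransferase Prmt1 at -3.51 ± 0.15 and the histone gene H2ac15 at -3.35 ± 0.15. The count was 912 and 1290 without day 1 replicate 1 and 2 and 2029 with scaled arrays, and the 20 genes at the extremes passed each time an array was left out. The hypoxia list lost its call without day 1 replicate 1 or 2 (adjusted p = 0.0809 and 0.0741) and the unfolded protein list without replicate 1 (0.13).

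**Figure D2:**
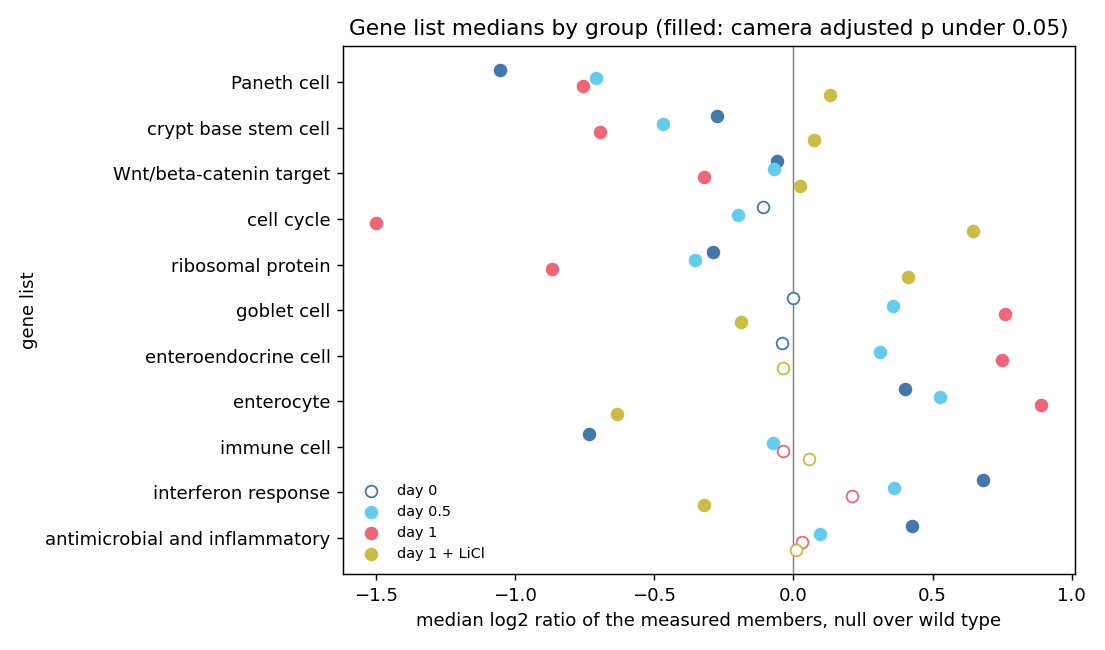
Median log ratio (taken as log2, null over wild type) of the measured genes of 11 gene lists in each of the 4 groups, with filled symbols where camera's adjusted p was under 0.05 at the preset correlation. The cell cycle list goes from -0.11 at day 0 to -1.499 at day 1 and 0.64 with LiCl, and the enterocyte list from 0.40 to 0.89 and -0.63.

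On the LiCl arrays, with the sign as deposited, proliferation genes were higher. Of 23 cell cycle genes 8 were higher (20 adjusted over the list alone, median 0.64), including Mcm5 at 1.14 ± 0.10 and Aurka at 0.97 ± 0.11. Ribosomal protein genes were higher for 2 of 15 (8 adjusted over the list alone, median 0.41), Rpl13 at 1.05 ± 0.13 and Rplp0 at 0.77 ± 0.10. Enterocyte genes were lower for 2 of 16 (11 adjusted over the list alone, median -0.63), Cyp3a11 at -0.97 ± 0.14 and Apoa1 at -0.71 ± 0.11. Camera adjusted p was 2.12e-20, 3.93e-09 and 4.29e-12, and each list had adjusted p = 0.0534 with an estimated correlation. By construction, the opposite sign of these arrays reverses every direction given for them here.

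Wnt target genes were higher with LiCl for 2 of 24 (3 adjusted over the list alone, median 0.03), Ccnd1 at 1.08 ± 0.10 and Ccnd2 at 0.76 ± 0.12, and stem cell genes for 1 of 15 (3 adjusted over the list alone, median 0.07), Slc12a2 at 0.66 ± 0.10. Lgr5 was at -0.04 ± 0.11. Here camera gave an adjusted p of 0.026 and 0.0156, with adjusted p = 0.243 and 0.219 with an estimated correlation. limma called 0 of 14 Paneth cell genes, with 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone, and Lyz1 was at 0.20 ± 0.14 (adjusted p = 0.767). The Paneth list shifted up (median 0.13, camera adjusted p = 0.026), with adjusted p = 0.367 with an estimated correlation. Hypoxia genes were lower for 2 of 13 (6 adjusted over the list alone, 1 of them higher, median -0.24), Ndrg1 at -1.03 ± 0.13 and Egln3 at -1.04 ± 0.14, with camera adjusted p of 0.000914 and adjusted p = 0.161 with an estimated correlation. The goblet cell (median -0.19), cholesterol (-0.15) and interferon (-0.32) lists shifted down with 0 genes called by limma, 5, 2 and 2 at an unadjusted p under 0.05, and 4, 1 and 2 adjusted over the list alone, 1 of the 4 goblet cell genes being higher. Their camera adjusted p was 0.0279, 0.0141 and 0.00282, with adjusted p = 0.243, 0.252 and 0.172 with an estimated correlation.

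limma called 390 genes on the LiCl arrays, 207 higher and 183 lower as deposited, of which 54 and 36 differed at least 2-fold. At the extremes were the nucleolar genes Gnl3 at 1.45 ± 0.15 and Fbl at 1.29 ± 0.11 and the intestinal hormone Fgf15 at 1.37 ± 0.15, and, in the other direction, Reg3a at -1.83 ± 0.10 (adjusted p = 0.0051) and Fabp6 at -1.70 ± 0.12. The count was 8 and 4 without LiCl replicate 1 and 2, 62 without either day 0 array, 206 without either day 1 array, 1653 with scaled arrays and 922 with the replicate block, and from the 2 LiCl arrays alone limma called 0 genes (2421 at an unadjusted p under 0.05). Of the 20 genes at the extremes 5 and 1 still passed without LiCl replicate 1 and 2, and 15 without either day 0 array. Without LiCl replicate 1 the Paneth (adjusted p = 0.586), Wnt target (0.297) and goblet lists (0.753) lost their calls, without replicate 2 the stem cell (0.242), cholesterol (0.242) and interferon lists (0.0598), and with the replicate block the unfolded protein list gained one (median -0.11, adjusted p = 0.0229).

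**Figure D3:**
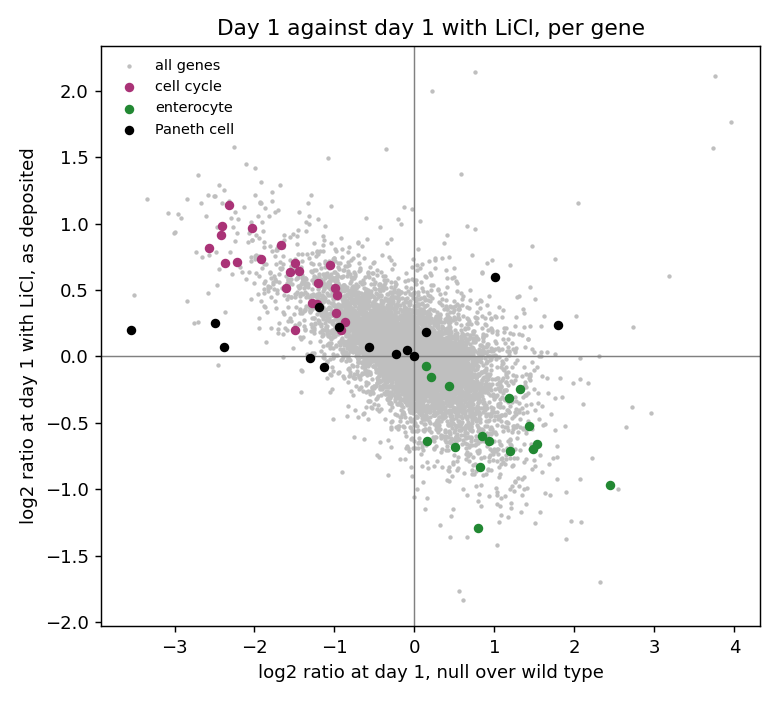
Log ratio of null over wild type (taken as log2) of each gene at day 1 (horizontal axis) and at day 1 with LiCl as deposited (vertical axis), with the members of the cell cycle, enterocyte and Paneth cell lists in colour. Over all genes r is -0.585, and Ccnd1 lies at -3.08 and 1.08.

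Genes called in 1 comparison recurred in others. Of the 185 genes higher at day 0, 92 were also higher at day 1 (17.3 for independent lists), and of the 152 lower genes 59 were also lower (16.9). For day 0.5 and day 1 the shared genes were 39 higher (3.9) and 22 lower (2.7). Against LiCl the directions were opposite as deposited: 174 genes were lower at day 1 and higher with LiCl (23.1) and 145 the reverse (17.2), while 14 were higher (19.4) and 2 lower (20.4) in both. Fisher's exact test gave 2.42e-133 and 8.63e-115 for the opposite overlaps, over genes that are not independent. The groups share 1 estimate of the spread and the dye term, so part of any excess may come from these. At day 0, 0.5 and 1 alike 22 genes passed, of which 9 were lower throughout (Lyz1, Defa3, Mmp7 and Ccnd1 among them), 11 higher throughout (Reg3b, Reg3g and Fabp6 among them) and 2 mixed.

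In the mean of the 4 groups, an average over groups whose ratios differ, Lyz1 was at -2.74 ± 0.07 and Reg3b at 2.53 ± 0.08. With the LiCl arrays as deposited, genes with the same sign on all 8 arrays included Nid1, a basement membrane protein, at 1.32 ± 0.08, the chaperone Hyou1 at 0.99 ± 0.06, Ubd at -1.09 ± 0.08, the Paneth cell ribonuclease Ang4 at -0.88 ± 0.08 and Lgr5 at -0.53 ± 0.06. A turned sign of the LiCl arrays would by construction end this agreement for each of these genes. With LiCl, Hyou1 was at 0.01 and Nid1 at 0.22, neither of them called there. A shared sign thus need not mean a difference in that group. Cell cycle genes were lower for 14 of 23 (17 adjusted over the list alone, median -0.30), stem cell genes for 7 of 15 (7 adjusted over the list alone, median -0.41), Wnt target genes for 8 of 24 (11 adjusted over the list alone, 1 of them higher, median -0.04) and immune cell genes for 4 of 11 (7 adjusted over the list alone, median -0.20). Ribosomal protein genes were lower for 7 of 15 (10 adjusted over the list alone, median -0.25). Of the Paneth cell genes 9 were lower and 1 higher (10 adjusted over the list alone, median -0.52). Enterocyte and enteroendocrine genes were higher for 9 each (10 and 9 adjusted over the list alone, medians 0.39 and 0.22). Camera called 16 lists, 10 up and 6 down. With an estimated correlation it called none (0 of 16), with adjusted p from 0.0638 to 0.163.

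limma called 1461 genes in this mean, 718 higher (49.1%) and 743 lower, of which 14 and 12 differed at least 2-fold. With the sign of the LiCl arrays turned it called 3509, 1671 higher and 1838 lower, 1328 of them shared, with Lyz1 at -2.84, Reg3b at 2.73 and Lgr5 at -0.51. List medians then were -0.65 for cell cycle, -0.48 for ribosomal protein, -0.63 for Paneth cell and -0.42 for stem cell genes. They were -0.16 for Wnt target, -0.18 for immune cell, 0.61 for enterocyte, 0.335 for enteroendocrine and 0.28 for goblet cell genes. The fetal-type (adjusted p = 0.0598) and immediate early lists (0.263) then lost their calls, and the cholesterol list gained one (median 0.15, adjusted p = 0.00846). The count was 701 and 187 without day 0 replicate 1 and 2, 946 without day 0.5 replicate 2, 825 and 492 without day 1 replicate 1 and 2, 642 without LiCl replicate 1, 2267 with the replicate block, and 430 with scaled arrays (62.1% higher). The goblet list (median 0.14) lost its call without day 0 replicate 2, day 1 replicate 2 or LiCl replicate 2 (adjusted p = 0.056, 0.0671 and 0.0658), while the immediate early list (median 0.06) lost its call without the latter 2 (0.098 and 0.074) or with the block (0.0521). With each pair averaged to 1 value, limma called 0 genes (664 at an unadjusted p under 0.05). These 664 are under the share of 0.05 of the 15123 genes that would pass on average without any difference.

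From day 0 to day 0.5 the ratio changed for 3 genes of the 11 called lists. Of 15 antimicrobial genes 2 fell, Saa3 at -2.18 ± 0.22 and Saa1 at -1.84 ± 0.19 (3 adjusted over the list alone, median -0.26), and Vim was the 1 mesenchyme gene of 13 that rose, by 1.35 ± 0.15 (1 adjusted over the list alone, median 0.12). Their camera adjusted p was 2.26e-05 and 0.0138. In the other 9 called lists limma called 0 genes. Immune cell genes shifted up (median 0.79, camera adjusted p = 3e-09), with 7 adjusted over the list alone and 7 unadjusted. Goblet (0.39), unfolded protein (0.25), fetal-type (0.46) and enteroendocrine genes (0.21) shifted up with 2, 2, 0 and 0 adjusted over the list alone and 3, 3, 4 and 5 unadjusted. Stem cell (-0.14), Wnt target (-0.09), cell cycle (-0.21) and interferon genes (-0.17) shifted down with 2, 4, 4 and 4 adjusted over the list alone, 1 of the 4 cell cycle genes in the other direction, and 4, 7, 7 and 4 unadjusted. Camera adjusted p lay between 0.000554 and 0.0241 for these 8. All 11 called lists had adjusted p from 0.169 to 0.452 with an estimated correlation.

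limma called 20 genes for this change, 11 that rose and 9 that fell, led by the chemokine Ccl24 at 2.29 ± 0.16 and Ndrg1 at 1.95 ± 0.19, and by Eef2 at -2.65 ± 0.17, whose probes disagreed, and Ada at -2.47 ± 0.26. The count was 0 without day 0 replicate 1, day 0.5 replicate 1 or either day 1 array (635, 1775 and 1175 at an unadjusted p under 0.05), 1 without day 0 replicate 2, 5 without either LiCl array, 0 with scaled arrays (1034 unadjusted), 116 with no dye term, 82 with day 0.5 replicate 2 taken as a dye swap and 56 with the replicate block, which also called the immediate early list (median -0.21, adjusted p = 0.0267). Of the 10 genes at the extremes 0 still passed in limma without either day 0 array, day 0.5 replicate 1 or either day 1 array, 2 without day 0.5 replicate 2 and 5 without either LiCl array. Calls of 5 lists ended without day 0 replicate 1 (adjusted p from 0.0581 to 0.108 for stem cell, enteroendocrine, fetal-type, cell cycle and unfolded protein genes), of the mesenchyme list without day 0 replicate 2 (0.091), of the mesenchyme and interferon lists without day 0.5 replicate 1 (0.0879 and 0.0536), and of stem cell, Wnt target, enteroendocrine and cell cycle genes without day 0.5 replicate 2 (from 0.0972 to 0.306).

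From day 0 to day 1, the ratio of 21 of 23 cell cycle genes fell (23 adjusted over the list alone, median -1.46), as with Mcm5 at -2.01 ± 0.14. It also fell for 6 of 15 stem cell (7 adjusted over the list alone), 6 of 24 Wnt target (7 adjusted over the list alone), 6 of 15 ribosomal protein (6 adjusted over the list alone) and 5 of 15 antimicrobial genes (7 adjusted over the list alone). Examples were Lgr5 at -0.86 ± 0.16, Ccnd1 at -2.41 ± 0.13 and Saa3 at -2.87 ± 0.20. Of 10 interferon genes 3 fell and 1 rose (4 adjusted over the list alone). The ratio rose for 6 of 12 goblet (7 adjusted over the list alone), 7 of 18 enteroendocrine (9 adjusted over the list alone, 1 of them lower), 4 of 16 enterocyte (7 adjusted over the list alone, 1 of them lower), 3 of 9 fetal-type (3 adjusted over the list alone), 6 of 11 immune (8 adjusted over the list alone) and 3 of 11 cholesterol genes (5 adjusted over the list alone), such as Zg16 at 1.90 ± 0.22, Vil1 at 1.22 ± 0.16 and Cd74 at 2.19 ± 0.24. Camera adjusted p for these 12 lists ran from 2.93e-23 for the cell cycle to 0.00707 for the interferon list, and from adjusted p = 0.0947 to 0.139 with an estimated correlation. limma called 1269 genes, 544 that rose and 725 that fell. The count was 110 and 168 without day 0 replicate 1 and 2, 252 and 454 without day 1 replicate 1 and 2, 493 with scaled arrays and 1964 with the replicate block, which also called the Paneth list (median 0.24, adjusted p = 0.0452).

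Between day 1 and day 1 with LiCl, a ratio of ratios that does not give the effect of LiCl on either genotype, all 23 cell cycle genes rose as deposited (23 adjusted over the list alone, median 2.12), with Mcm5 at 3.46 ± 0.14. So did 13 of 15 ribosomal protein (13 adjusted over the list alone), 8 of 15 stem cell (9 adjusted over the list alone) and 10 of 24 Wnt target genes (10 adjusted over the list alone), among them Lgr5 at 1.05 ± 0.16 and Ccnd1 at 4.16 ± 0.13. Of the Paneth cell genes 7 rose and 1 fell (9 adjusted over the list alone, 8 of them upward), Lyz1 by 3.74 ± 0.20. The ratio fell for 13 of 16 enterocyte (14 adjusted over the list alone), 11 of 18 enteroendocrine (12 adjusted over the list alone), 6 of 12 goblet (6 adjusted over the list alone), 5 of 11 cholesterol (7 adjusted over the list alone) and 2 of 10 interferon genes (6 adjusted over the list alone, 1 of them upward), and for most called genes of the p53 (6 of 7), unfolded protein (4 of 5) and hypoxia lists (4 of 5), where 7, 5 and 7 passed adjusted over the list alone, 6, 4 and 5 of them downward. Camera adjusted p ran from 2.94e-22 for the cell cycle to 0.0238 for the interferon list, and from adjusted p = 0.0501 to 0.174 with an estimated correlation.

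limma called 2856 genes between day 1 and day 1 with LiCl, 1566 that rose and 1290 that fell as deposited. With the sign of the LiCl arrays turned it called 1033 (566 and 467), 797 of them shared, with Ccnd1 at 2.01, Mcm5 at 1.18, Lyz1 at 3.34, Lgr5 at 1.13 and Cyp3a11 at -1.48. The cell cycle list then stood at a median of 0.87 (adjusted p = 2.49e-19) and the enterocyte list at -0.28 (0.00171), while the unfolded protein (0.292), hypoxia (0.62) and interferon lists (0.85) lost their calls and the fetal-type list gained one (median -0.79, 4.08e-05). The count was 1484 and 1735 without day 1 replicate 1 and 2, and the interferon list lost its call without day 1 replicate 2 or LiCl replicate 2 (adjusted p = 0.0694 and 0.0533).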

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

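All tests of explanations in this part were chosen after the values were seen, while the tests of the 3 changes of the ratio were planned. The ratio of null over wild type differed between groups, by the fitted difference, for 20 genes and 11 lists from day 0 to day 0.5, for 1269 genes and 12 lists from day 0 to day 1, and for 2856 genes and 13 lists between day 1 and day 1 with LiCl. From day 0 to day 0.5 the genes with the largest changes were Ccl24 (2.29), Vmn1r215 (2.02), Ndrg1 (1.95), Fibcd1 (1.76) and Car5a (1.65), and in the other direction Eef2 (-2.65), Ada (-2.47), Saa3 (-2.18), Slc6a14 (-2.10) and Saa1 (-1.84). From day 0 to day 1 these were Prl2c2 (3.98), Prl2c3 (3.65), Prl2c5 (3.61), Prl2a1 (3.14) and Cyp1a1 (2.90), and Eef2 (-3.53), H2ac15 (-3.41), H2ac12 (-3.14), H2ac22 (-2.98) and Saa3 (-2.87). Between day 1 and day 1 with LiCl they were H2ac15 (4.54), Ccnd1 (4.16), Bex1 (4.07), Pbk (4.04) and H2ac22 (4.04), and Fabp6 (-4.02), S100g (-3.55), Cyp3a11 (-3.41), Reg3b (-3.38) and Ces2a (-3.32). With the LiCl sign turned the last 10 kept their direction and their call, with Ccnd1 at 2.01 and Fabp6 at -0.62 (adjusted p = 0.041).

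Among probes outside the comparisons, 950 of 12773 mouse probes without a gene name passed at day 1 (7.44%), against 3915 of 22305 probes with one (17.55%) and 0.14% to 17.04% in the 8 control series. The control series include 1 of 97 in the mCN series and 65 of 392 in mCP and 53 of 311 in mCT. Of the mCP and mCT probes 140 and 250 carry a gene name, so these series are not free of gene probes. Series with 0 named probes had 0.14% (mCD), 1.03% (mCN), 5.03% (mVI) and 5.41% (mTG). Named probes did not always go with a high share: mCM, with 216 of 540 named, had 1.11%. A control-series probe, mTG036009, stood at 1.24 at day 0 (SE 0.169, limma adjusted p = 0.017), the only 1 of 37 mTG probes called there. A second, mTG036032, was at 1.40 (SE 0.291, limma adjusted p = 0.0786). On LiCl replicates 1 and 2 the first lay at -0.24 and -0.06 and the second at -0.03 and -0.11. What these 2 probes detect was not tested. Another control-series probe, mCD037412, stood at 6.18 on LiCl replicate 1 and 0.04 on replicate 2. It was 1 of 7 of the 1384 mCD probes that lay between 1.22 and 6.18 on LiCl replicate 1, against 0 at least 2-fold from equal on replicate 2, while day 0.5 replicate 1 also had 7 such probes, with a highest value of 2.15.

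The ratios of the LiCl arrays ran opposite to those of day 1, with Ccnd1 at -3.08 at day 1 and 1.08 with LiCl and Fabp6 at 2.32 and -1.70. A turned sign stays open: of 20 genes that passed in 1 direction at all 3 times, 17 had the opposite sign with LiCl, 4 of the 5 called there among them. The median of their LiCl value over their 3-day mean was -0.105 (95% bootstrap interval over genes -0.297 to -0.05), and a LiCl effect of unknown size may have moved it in either case. That interval resamples genes, which are not independent, and does not measure the spread between samples. For 13 of the 20 genes the LiCl value over the 3-day mean lay near 0, between -0.211 and 0.132. The sign with LiCl therefore says little for most of the 20. If the other channel is wild type, LiCl may have brought null crypts just to that level. At day 1 and on the LiCl arrays 319 genes were called in opposite directions and 16 in the same direction. Independent lists give 40.2 opposite calls, but genes that vary together are not independent. The LiCl calls also rest on the spread shared with the other groups, since the 2 LiCl arrays alone gave 0 calls. These counts therefore do not decide it. The same median is also near what RNA of 1 genotype in both channels might give (Lyz1 at 0.20, H2-Ab1 at 0.06). For the same reasons the 319 opposite calls do not decide this, with both channels treated alike or unlike. A response of the null crypts to LiCl that passes the wild-type level for part of the genes stays open too.

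MHC class II genes were lower in null crypts at day 0, with 7 of 7 past the threshold and a median of -2.59, against -1.17 at day 0.5, -0.40 at day 1 and -0.00 with LiCl. A variant of the H2 region as the whole cause is argued against by Cd74, a gene of another chromosome, at -2.61 (SE 0.168). The interferon response list was higher (median 0.68, camera adjusted p = 6.69e-11). That was known beforehand and speaks only for the genes of that list. Ubd and Ido1, both induced by interferon gamma, were lower. A lower response to interferon gamma stays open and was not tested. Fewer leukocytes in the null crypts may account for part, since the other 8 immune cell genes, some of which epithelial cells could also express, had a median of -0.61 and limma's camera called this set. A strain variant under the probes cannot be told apart for these 7 genes. They rose from day 0 to day 1 by a median of 2.19 (interval 1.67 to 2.40, over genes and not over samples). Without intensities a loss of signal in both channels would look alike. A lower expression of MHC class II in the epithelium of the null crypts stays open and was not tested.

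Replicate 1 minus replicate 2 differences were shared by the groups, with correlations over all probes from 0.23 to 0.242 in the 3 pairs without LiCl, and with LiCl from 0.176 to 0.222 as deposited but from -0.222 to -0.176 with its sign turned. A dye bias of the probes with the dyes as labelled is argued against, as the whole cause, by correlations of 0.24 and 0.23 of day 0.5 with day 0 and day 1, since both day 0.5 arrays carry the null RNA in the same labelled dye and should then lie near 0. A dye or batch component that follows the replicate number remains a candidate explanation for these 3 groups, as their lowest correlation was 0.23, and with LiCl it depends on the sign. No biological explanation was tested. With the replicate block beside the dye term limma called 610 genes at day 0 and 3829 at day 1.

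For the mean of the 4 groups, 3 of the 8 splits that exchange null and wild type in whole groups gave at least the real 1461 genes, the real one included, and 8 splits are too few for a share under 0.05. The highest other value, 2963, came from exchanging the LiCl group with its dyes, which points to a structure of the samples. Of 100 drawn exchanges of single arrays 2 gave as many, but these part pairs of arrays that correlate, so nothing is concluded from them.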

How the results depend on the processing

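The alternatives with the sign of the LiCl arrays turned, with those arrays left out, and with a replicate block in place of the dye term were chosen after the data were seen. Of 18389 values of named genes under an alternative, 16729 kept their side of the threshold, 1207 no longer passed, 446 came to pass and 7 reversed. A change of direction counts as reversed only where the main or the alternative value passed. Turns between values that both failed count as kept, as does any gene that failed in both. List members were named whether or not they passed, and many alternatives leave out an array of another group. The share kept is therefore not the share of calls that held. For gene lists 3278 of 3497 kept their side, with 175, 43 and 1 for the other outcomes in that order (by camera's direction). No centring, each probe alone and robust eBayes moved no count of genes by over 1.5 times. For the other settings the cause was not tested, except where stated. With no dye term limma called 341 genes at day 0.5 (main 66) and 116 for the change from day 0 to day 0.5 (main 20), and with day 0.5 replicate 2 taken as a dye swap 321 and 82. With the replicate block beside the dye term it called 610 at day 0 (main 337), 237 at day 0.5, 922 with LiCl (main 390), 2267 in the mean of the groups (main 1461), 56 for the change from day 0 to day 0.5 and 1964 from day 0 to day 1 (main 1269). The block ended the call of 0 named genes, brought 72 past the threshold, and beyond the 4 lists given with their comparisons it changed no other call of a list. In place of the dye term it gave 905, 848, 1037, 2753, 227 and 2223 for these 6 comparisons. With arrays scaled to equal spread the counts were 160 at day 0, 24 at day 0.5, 2029 at day 1 (main 3103), 1653 with LiCl, 430 in the mean, 0 from day 0 to day 0.5 (1034 at an unadjusted p under 0.05) and 493 from day 0 to day 1. From the arrays of the group alone limma called 646 at day 0 and 0 with LiCl (2421 unadjusted), and 2-fold in both arrays were 85, 622 and 55 genes at day 0, day 1 and with LiCl, a rule with no test. In the mean, averaged pairs gave 0 (664 unadjusted, fewer samples by construction) and the 3 groups without LiCl 2820, where averaged pairs gave 0 (2375 unadjusted). The 664 are under a share of 0.05 of the 15123 genes and the 2375 above it. Without the LiCl arrays 5 genes passed from day 0 to day 0.5. Camera with an estimated correlation called 4 lists over all comparisons (main 101), and over the other alternatives, left-out arrays apart, the number was from 91 to 103. With the LiCl sign turned, which reverses values by construction, 3509 genes passed in the mean and 1033 between day 1 and day 1 with LiCl (main 2856). Reversed were Anxa1 in the mean (-0.023), and between day 1 and LiCl Jag1 (-0.156), Phlda3 (-0.014), Chac1 (0.048), Reg3a (1.222), Car9 (0.144) and Rpl13 (-0.438), while camera's direction turned for the interferon list (adjusted p = 0.85) although its median stayed below 0 (-0.022, main -0.504). With each array left out in turn, where a lone array is assumed to vary like the other groups, counts ran from 26 to 305 at day 0, 9 to 50 at day 0.5, 912 to 3270 at day 1, 4 to 301 with LiCl, 187 to 1444 in the mean, 0 to 16 from day 0 to day 0.5 (0 at 635 to 1775 unadjusted), 110 to 1358 from day 0 to day 1, 1484 to 2824 between day 1 and LiCl, and 96 to 100 called lists. A filter that asks for a value on at least 1 array was not run, since no value was missing. Signal over background is unknown, so weak probes could not be told from strong ones.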

Other observations

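The gene families and the test of the genes near Lgr4 were chosen after the values were seen. The families were picked after the shift of the ribosomal list, or after some of their members had been seen at the extremes, so their genes are counted and no family test is given. In null crypts at day 1, 63 of 80 cytosolic ribosomal protein genes (Rpl and Rps, which hold the 15 of the list) were lower and 1 higher (median -0.75), and 54 of 75 mitochondrial ribosomal protein genes (Mrpl and Mrps) were lower (median -0.67). Of 47 translation initiation factor genes (Eif) 24 were lower and 3 higher (median -0.42), and of 20 RNA polymerase genes (Polr) 11 were lower (median -0.59). The chaperonin genes (Cct) were lower for 6 of 9 and higher for 1 (median -0.81), and the H2A histone genes (H2ac) lower for 9 of 15 and higher for 2 (median -2.47). On the LiCl arrays, as deposited, 7 Rpl and Rps genes (median 0.35) and 7 H2ac genes (median 0.93) were higher.

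Of 70 cytochrome P450 genes (Cyp) 20 were higher at day 1 (median 0.15), such as Cyp3a13 at 1.79 ± 0.13. Of 21 glutathione transferase genes (Gst) 12 were higher and 1 lower (median 0.72), with Gstm6 at 1.57. Carboxylesterase genes (Ces) were higher for 6 of 11 (median 0.66), with Ces2a at 2.08 at day 1 and -1.24 with LiCl. Glucuronosyltransferase genes (Ugt) were higher for 8 of 19 (median 0.23) and aldehyde dehydrogenase genes (Aldh) for 7 of 20 (median 0.26). On the LiCl arrays 14 Cyp, 4 Gst, 6 Ces, 4 Ugt and 4 Aldh genes were lower as deposited, a direction that the opposite sign of these arrays would reverse. The prolactin family, with 4 of 21 genes higher both at day 1 and, as deposited, on the LiCl arrays, holds near-identical copies.

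Sequence differences around the targeted gene could make genes near Lgr4 differ, since the null allele brings the flanking DNA of its origin. Within 10 Mb of Lgr4 on the GRCm38.p6 assembly, 2 of 140 genes passed at day 0 (1.43%), against 335 of 14983 others (2.24%). Fisher's exact test gave an odds ratio of 0.634 (95% interval 0.076 to 2.351, p = 0.773), which excludes neither an excess nor its absence.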
